A study of Homo sapiens with 12 samples.

How the data were processed

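RNA of 12 libraries was analysed, 3 in each of 4 groups: parental OCI-LY1 cells and venetoclax-resistant OCI-LY1R cells, each with vehicle or 1 µM decitabine for 3 days. Per the labels' protocols the libraries were stranded, of polyadenylated RNA, and sequenced on the DNBSEQ platform. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used with build hg38. Their versions, their order, the annotation release and the strand setting are not given in the sources used here.

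The deposited tables, 1 per cell line, hold decimal values with no unit in the header. They were read as TPM scaled by the authors within each library, since each library sums to 1000000 and StringTie, named in the submitters' processing notes, writes TPM. Both tables list the same features in the same order. TPM keep no library size, so depth is unknown and neither counting intervals nor floors are given. The design written before the data were examined was for counts, and its branch for normalised values was used instead. An exact 0 was read as listed at 0, since genes that every cell uses are also at 0 in some libraries: UBB was listed at 0 in 3 libraries and at 1543 to 2706 TPM in the others.

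Gene names were used and not the identifiers of the parental table, because only 24.1% of those identifiers belong to the name beside them. The ribosomal protein genes had a median of 1354.2 TPM in parental decitabine replicate 3 by name and 0.15 TPM by identifier. Names that occur once (59490) were kept and 1166 features with repeated names left out. Positions, classes and strands come from GENCODE 29 (GRCh38), in which 54865 names were found once. H2BC12, H4C9 and RFX5-AS1 were not found there and have no coordinates here. Columns of the parental table were matched to samples by title. Columns of the resistant table were matched to groups by table name and treatment and are lettered a, b and c.

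Each comparison was tested with limma 3.58.1 (trend) in R 4.3.3 on log2(TPM + 1), over features with a mean of at least 1 TPM in the fitted libraries, with a Benjamini-Hochberg adjusted p under 0.05. A fold change is on that scale and understates the change of features of low TPM. No fold is given against a group listed at 0 in every library. The comparisons were decitabine against vehicle in each line, resistant against parental cells under vehicle, and the difference of the 2 responses in a model of 4 group means. The design allowed the test between lines only for raw counts on one scale, and running it on TPM was a relaxation decided after the files were seen. The shared direction was measured by correlation and by overlap of calls with the 2-sided Fisher's exact test. The overlap with the resistance difference was set against n1 × n2 / N. The covariance was set against 100 simulated sets of unchanged groups that share a vehicle group in the same way.

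The text names features by a rule fixed before the data were examined: the 6 largest rises and falls and the 4 rises and 4 falls of smallest adjusted p among called features without overlap between groups, 14 core genes of apoptosis and DNA methylation, and up to 4 members of a described list with those that go the other way. For the difference between the lines the condition on overlap was not applied. Not all features the rule allows are named, clone names are not printed, and the result of 1 core gene is not reported here. Leaving out replicate 3 of the parental decitabine group was written down beforehand, and the rule was also applied to that fit after its effect was seen. The 27 fixed gene lists and 4 marker lists were tested or summed as written beforehand; camera with a preset correlation of 0.01 was used, with camera's estimated correlation and fry as alternatives, for lists with at least 3 tested members.

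Alternatives were quantile scaling, no filter, a mean of at least 5 TPM, a pseudocount of 0.1, an adjusted p under 0.01, a limit of 2-fold, the replicate number as a block in parental cells, and leaving out each library in turn. Median-ratio scaling outside the list tests, features above 0 in every fitted library, and list tests without replicate 3 were added after the data were seen. Opposite-strand overlap was computed from exons, and features with at least 80% of their exon length opposite a gene and a mean of at least 5 TPM were used for the correlation with the opposite gene.

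The test was tried on simulated data with 200 changed features, 50 per size, at log2 changes of 1, 2, 3 and 4. Noise was normal and independent with each feature's spread, and changes were placed only in features of higher mean value. Values that switch between 0 and high were not modelled. In the real data 47.1% of the resistant calls and 54.3% of the parental calls without replicate 3 had a library at 0. The shares below may therefore not hold for the real calls. It recovered 30%, 56%, 88% and 90% for the resistant comparison (8579 features, 8 false among 140 calls) and 22%, 70%, 80% and 92% for parental cells without replicate 3 (8120 features, 11 false among 143 calls). For resistant against parental cells it recovered 34%, 70%, 76% and 90% (7760 features, 8 false among 143 calls), and for the difference between the lines without replicate 3, 16%, 50%, 70% and 88% (8505 features, 10 false among 125 calls). Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.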

Results

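Polyadenylated RNA was sequenced in 12 libraries of OCI-LY1 cells, a human diffuse large B-cell lymphoma line of germinal-centre type. The 4 groups held 3 libraries each: parental cells and a venetoclax-resistant derivative, OCI-LY1R, both given either vehicle (DMSO) or 1 µM decitabine for 3 days. Venetoclax inhibits the survival protein BCL2, and resistant cells had been selected with rising concentrations up to 1 µM. Decitabine is a deoxycytidine analogue that inhibits DNA methyltransferases. Values are TPM, a length-normalised abundance of each annotated feature, and sum to 1000000 in each library. The depth of each library is unknown, so no counting intervals are given. The labels do not state whether replicates were separate cultures, so the p-values measure the spread between these libraries, which can be technical. Parental libraries carry their replicate numbers, and resistant libraries are lettered a, b and c within each group.

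Replicate 3 of the parental decitabine group stood apart from the other 11 libraries in which features carried the signal. ACTB was listed at 6353 TPM in replicate 3 and at 8.14 to 20.4 TPM in the other 11, EEF1A1 at 2688 against 1.59 to 21 TPM, RPLP0 at 2956 against 0.34 to 5.85 TPM and CD79A at 1491 against 3.39 to 8.74 TPM. Protein-coding features took 89.4% of TPM in replicate 3 and 26.6% to 32.2% in the others, and features annotated as antisense took 0.30% against 34.9% to 48.7%. The feature lying opposite GAPDH was listed at 1.17 TPM in replicate 3 and at 81929 to 205205 TPM in the others. On the mitochondrial genome, minus-strand features took 0.44% of TPM in replicate 3 and 12.99% to 31.83% in the others, while plus-strand features took 32.52% against 0.60% to 2.34%. Across 334 features that lie on the opposite strand of a gene, the mean of the 11 libraries correlated with the opposite gene's level in replicate 3 (Spearman rho 0.641) more than with the same feature's level there (0.104). These correlations are across features, which are not independent replicates. In the other 11 libraries a value is that of the named feature as listed, and for many coding genes it was far below that in replicate 3. Fits without replicate 3 keep libraries that resemble each other, which does not make these the sounder ones. Strand may have been assigned oppositely in replicate 3 and in the 11. If so, these values argue against replicate 3 as the one assigned to the wrong strand. Antisense features took 34.9% to 48.7% of TPM in the 11, and ACTB was at 20.4 TPM or less there. The 11 would then be those on the wrong strand, and the fits below rest mostly on them. Replicate 3 had 13701 features of at least 1 TPM and the others 7137 to 9117. Among the 11, decitabine libraries had more such features than vehicle libraries of the same line. Parental cells had 7332 to 7386 under vehicle and 8306 and 8250 in decitabine replicates 1 and 2. Resistant cells had 7137 to 7405 under vehicle and 8804 to 9117 under decitabine. For the rises given below only the scalings bear on this library-wide shift. How far it carries the shared direction was not tested.

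**Figure D1:**
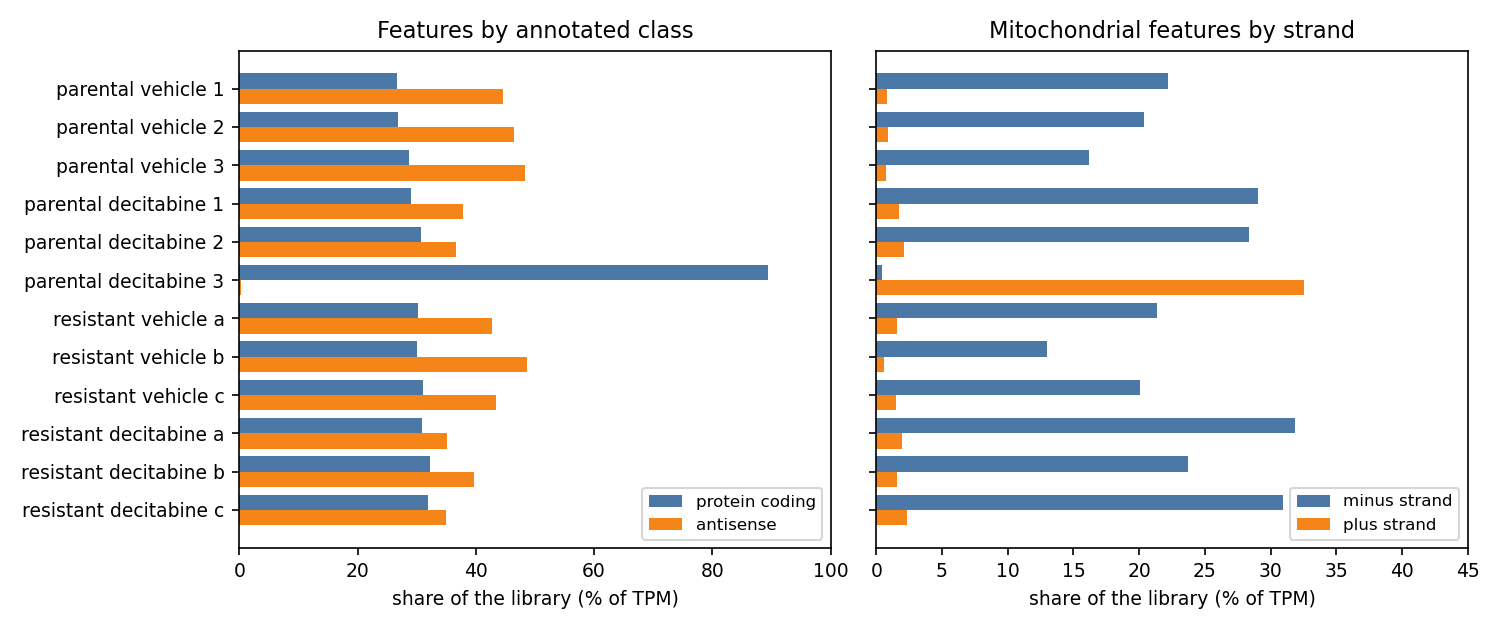
Share of each library's TPM (%, horizontal axes) in features annotated as protein coding or antisense (left) and in mitochondrial features on the minus or plus strand (right), 1 pair of bars per library. Parental decitabine replicate 3 has 89.4% in protein-coding features, and the other 11 libraries have 26.6% to 32.2%.

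**Figure D2:**
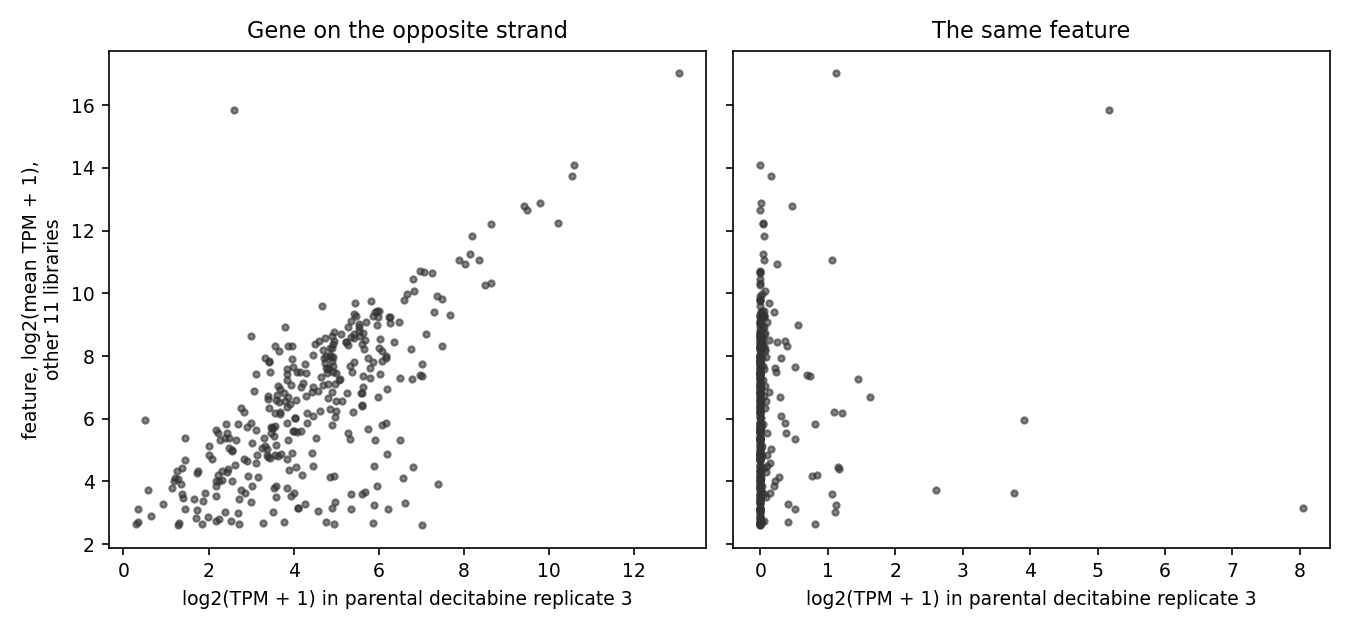
Each point is 1 of 334 features on the opposite strand of a gene, with log2(mean TPM + 1) over the 11 other libraries on the vertical axis against log2(TPM + 1) in parental decitabine replicate 3 of the opposite gene (left) or of the same feature (right). Spearman rho is 0.641 on the left and 0.104 on the right.

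Decitabine against vehicle in parental cells addresses what the drug changes in cells that were not selected with venetoclax. Without replicate 3, 112 features rose and 39 fell with decitabine among 8122 tested. Features above 0 numbered 10228 to 10426 in the vehicle libraries and 11720 and 11230 in decitabine replicates 1 and 2. UQCR10, a subunit of mitochondrial complex III, was among the rises, and UQCRQ, another subunit of the same complex, was among the falls. UQCRQ was also listed at 0 in some resistant libraries with and without the drug. Of 13 transcripts encoded by the mitochondrial genome 6 were called as rises, and all 6 lost their calls without any 1 vehicle library. If strand was assigned oppositely, these rises may not be those of the transcripts. KLRK1, the gene of the immune receptor NKG2D, was listed at 0 under vehicle and above 30 TPM under decitabine.

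UQCR10 (chromosome 22, 29767369 to 29770413, GRCh38) was listed at 0 in all 3 parental vehicle libraries, at 342 and 304 TPM in decitabine replicates 1 and 2 and at 141 TPM in replicate 3 (adjusted p = 0.00279 without replicate 3). TMEM205 (chromosome 19, 11342776 to 11346518) was listed at 0 in the vehicle libraries, at 185 and 232 TPM in replicates 1 and 2 and at 81.9 TPM in replicate 3 (limma adjusted p = 0.0037). Of its length 41.4% lies opposite CCDC159. In resistant cells it was at 0 in 2 of 3 vehicle and 0 of 3 decitabine libraries. MID1IP1-AS1 (chromosome X, 38801568 to 38803883) was listed at 0 under vehicle and at 58.4 and 47.2 TPM in decitabine replicates 1 and 2 (adjusted p = 0.00667), with 0.40 TPM in replicate 3. PRAL (chromosome 17, 6772831 to 6776116), which lies over 77.1% of its length opposite the interferon-stimulated gene XAF1, rose from 22.7, 20.3 and 20.03 TPM to 264 and 302 TPM (log2 fold change 3.69, SE 0.13, adjusted p = 0.00453), and was listed at 0 in replicate 3. KLRK1 (chromosome 12, 10372353 to 10391874) was listed at 0 in the vehicle libraries and at 33.7 and 38.3 TPM under decitabine, with 28.7 TPM in replicate 3 (adjusted p = 0.0074). UQCRQ (chromosome 5, 132866560 to 132868031) fell from 275, 196 and 434 TPM under vehicle to values listed at 0 in both decitabine replicates (limma adjusted p = 0.00667). It was at 66.3 TPM in replicate 3. In resistant cells UQCRQ was listed at 0 in 1 of 3 vehicle and 2 of 3 decitabine libraries, and so also without the drug. RASA4 (chromosome 7, 102573807 to 102616757), a Ras GTPase-activating protein gene with near-identical copies and so of uncertain assignment, fell from 152, 129 and 134 TPM to 7.11 and 8.20 TPM (log2 fold change -4.01, SE 0.15, adjusted p = 0.00453), with 18.5 TPM in replicate 3. BCL2 was at 53.8, 55.9 and 52.8 TPM under vehicle and at 75.0 and 88.6 TPM under decitabine (log2 fold change 0.58, SE 0.13, adjusted p = 0.12 over all features, 0.0224 adjusted over the list alone). KLRK1 lost its call without vehicle replicate 1 (adjusted p = 0.0526, 0.00647 to 0.39 over its alternatives), and so did UQCRQ (0.0559, range 0.0051 to 0.594).

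All 13 mitochondrially encoded transcripts were tested, and 12 had a positive log2 fold change, with a median of 1.07 against 0.21 for all features. By limma, 6 of the 13 rose over all features tested, and 11 rose when adjusted over the list alone. MT-ATP6 (2.24), MT-ND2 (1.63), MT-ND1 (1.58), MT-CO2 (1.15), MT-ND5 (1.07) and MT-ND6 (0.88) were the 6, and MT-ND4 went the other way (-0.03). Levels in the 11 libraries departed from replicate 3 in both directions. MT-CO2 was at 185 to 626 TPM in the 11 and at 57348 TPM in replicate 3, and MT-ND6 at 28082 to 88637 against 610 TPM. Members of the list may thus be affected oppositely if strand was assigned oppositely. The camera test with a preset correlation called this list (adjusted p = 1.68e-05 over 22 lists) and none of the other 21 (2 at an unadjusted p under 0.05). Fry called it too (fry adjusted p = 0.0135), while camera with an estimated correlation did not (adjusted p = 0.644). Without vehicle replicate 1, 2 or 3 all 6 lost their calls: adjusted p was 0.117, 0.121 and 0.109 for MT-CO2, 0.124, 0.126 and 0.124 for MT-ND2, 0.117, 0.121 and 0.0934 for MT-ND1, 0.122, 0.0689 and 0.0912 for MT-ATP6, 0.129, 0.158 and 0.133 for MT-ND5 and 0.0598, 0.162 and 0.11 for MT-ND6. Without decitabine replicate 1 or 2 MT-ND1 (0.0694 and 0.0985), MT-ATP6 (0.106 and 0.13) and MT-ND6 (0.186 and 0.187) lost theirs, and MT-ND5 without replicate 2 (0.0561). MT-ND6 had an adjusted p of 0.0513 under quantile and 0.0846 under median-ratio scaling, and its direction turned with replicate 3 included (-1.38, adjusted p = 0.786). With median-ratio scaling the list's median was 0.88 and that of all features 0.06.

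With replicate 3 included, limma called 0 of 13778 features in parental cells (262 at an unadjusted p under 0.05), and UQCR10 had an adjusted p of 0.0998 (0.00328 to 0.389 over its alternatives). Without replicate 3, leaving out vehicle replicate 1, 2 or 3 as well gave 14, 23 or 47 calls in place of 151, and leaving out decitabine replicate 1 or 2 gave 231 or 264. With no filter 35 were called, and 23 at an adjusted p under 0.01. In 74 of the 151 calls (49.0%) every library of 1 group was listed at 0. All 151 separated the groups without overlap, as did 3203 of the 8122 features tested (39.4%, with 20% by chance). The median log2 fold change of all features was 0.21, 0.05 under median-ratio scaling (105 rose and 88 fell) and -0.02 under quantile scaling (75 rose and 47 fell).

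Decitabine against vehicle in resistant cells addresses what the drug changes once cells tolerate venetoclax. Here 243 features rose and 65 fell among 8579 tested. Features above 0 numbered 9695 to 9927 in the vehicle and 12590 to 13130 in the decitabine libraries. Minus-strand mitochondrial features took 12.99% to 21.38% of TPM under vehicle and 23.69% to 31.83% under decitabine. Rises made up 78.9% of calls as deposited, 64% under median-ratio and 66.8% under quantile scaling, so part of the excess went with the scaling. What further part this library-wide shift has in the excess of rises was not tested. The value listed for BCL2, the target of venetoclax, rose in resistant cells given decitabine, but lost its call when any 1 library was left out. Values listed for the death receptor gene FAS, the deoxynucleotide hydrolase gene SAMHD1, the meiotic gene SYCP3 and the histone genes H4C9 and H2BC12 rose. Those of the peroxiredoxin gene PRDX2 and the pyruvate dehydrogenase kinase gene PDK1 fell. If strand was assigned oppositely, values of coding genes here may not be those of the genes.

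BCL2 (chromosome 18, 63123346 to 63320128) rose from 37.1 ± 2.48 to 75.5 ± 3.26 TPM (SD, n = 3 each). The log2 fold change was 1.01 (SE 0.13, limma adjusted p = 0.0247), with higher values in 3 of 3 decitabine libraries. BCL2 has no annotated exon on the opposite strand and was at 169.9 TPM in parental decitabine replicate 3. Coding genes of at least 20 TPM in replicate 3 without such overlap were mostly far lower in the other libraries (median log2 ratio -5.09). If strand was assigned oppositely, values of BCL2 and other coding genes here may not be those of the gene. FAS (chromosome 10, 88990582 to 89015785) rose from 10.99 ± 3.73 to 77.2 ± 16.3 TPM (SD, n = 3 each; log2 fold change 2.73, SE 0.28, adjusted p = 0.0127), and 8.9% of it lies opposite ACTA2. SAMHD1 was listed at 0 in the vehicle libraries and at 15, 15.8 and 16.04 TPM under decitabine (adjusted p = 0.0026). SYCP3 rose from 16.2, 7.94 and 13.7 TPM to 91.5, 166 and 68.3 TPM (log2 fold change 2.96, SE 0.41, adjusted p = 0.0271). H4C9 rose from 50.1, 69.9 and 57.8 TPM to 260, 262 and 224 TPM (log2 fold change 2.06, SE 0.17, adjusted p = 0.00638), and H2BC12 was listed at 0 in the vehicle libraries and at 227, 254 and 195 TPM under decitabine (adjusted p = 0.000173). PAFAH1B3 (chromosome 19, 42297033 to 42303546), listed at 0 under vehicle, was at 48.8, 56.6 and 96.6 TPM under decitabine (limma adjusted p = 0.00172). In parental vehicle libraries it was listed at 0 in 1 of 3, with a mean of 51.5 TPM. KLRK1 was again listed at 0 under vehicle and at 27.6, 37.4 and 44.2 TPM under decitabine (adjusted p = 0.00172). PRDX2 (chromosome 19, 12796820 to 12801859) fell from 626, 749 and 1387 TPM to values listed at 0 in all 3 decitabine libraries (limma adjusted p = 0.000446). In parental cells it was also listed at 0 in vehicle replicate 2 and decitabine replicate 2. In parental decitabine replicate 3 PRDX2 was at 714 TPM and the feature opposite it at 0. That feature had a mean of 6436 TPM in the other 11 libraries, so the fall listed for PRDX2 may not be that of the gene. GPANK1 fell from 16.6, 23.6 and 25.2 TPM and TMEM217 from 12.9, 11.7 and 9.03 TPM, both to values listed at 0 (adjusted p = 0.0026 and 0.00658). PDK1 fell from 82.1, 57.2 and 50.4 TPM to 11.6, 13.8 and 13.5 TPM (log2 fold change -2.18, SE 0.23, adjusted p = 0.0127). BCL2 lost its call when any 1 library was left out: adjusted p was 0.0529, 0.0543 and 0.0816 without vehicle a, b and c and 0.0784, 0.0726 and 0.0642 without decitabine a, b and c (0.0275 to 0.0816 over its alternatives, log2 fold change 0.87 to 1.05). FAS lost its call without decitabine a (adjusted p = 0.0518, range 0.0163 to 0.0518), PDK1 without decitabine a and c (0.0512 and 0.0519, range 0.0103 to 0.0519), and SYCP3 without vehicle b and c (0.0667 and 0.0812) and decitabine a, b and c (0.0858, 0.0573 and 0.0542, range 0.0274 to 0.0858).

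**Figure D3:**
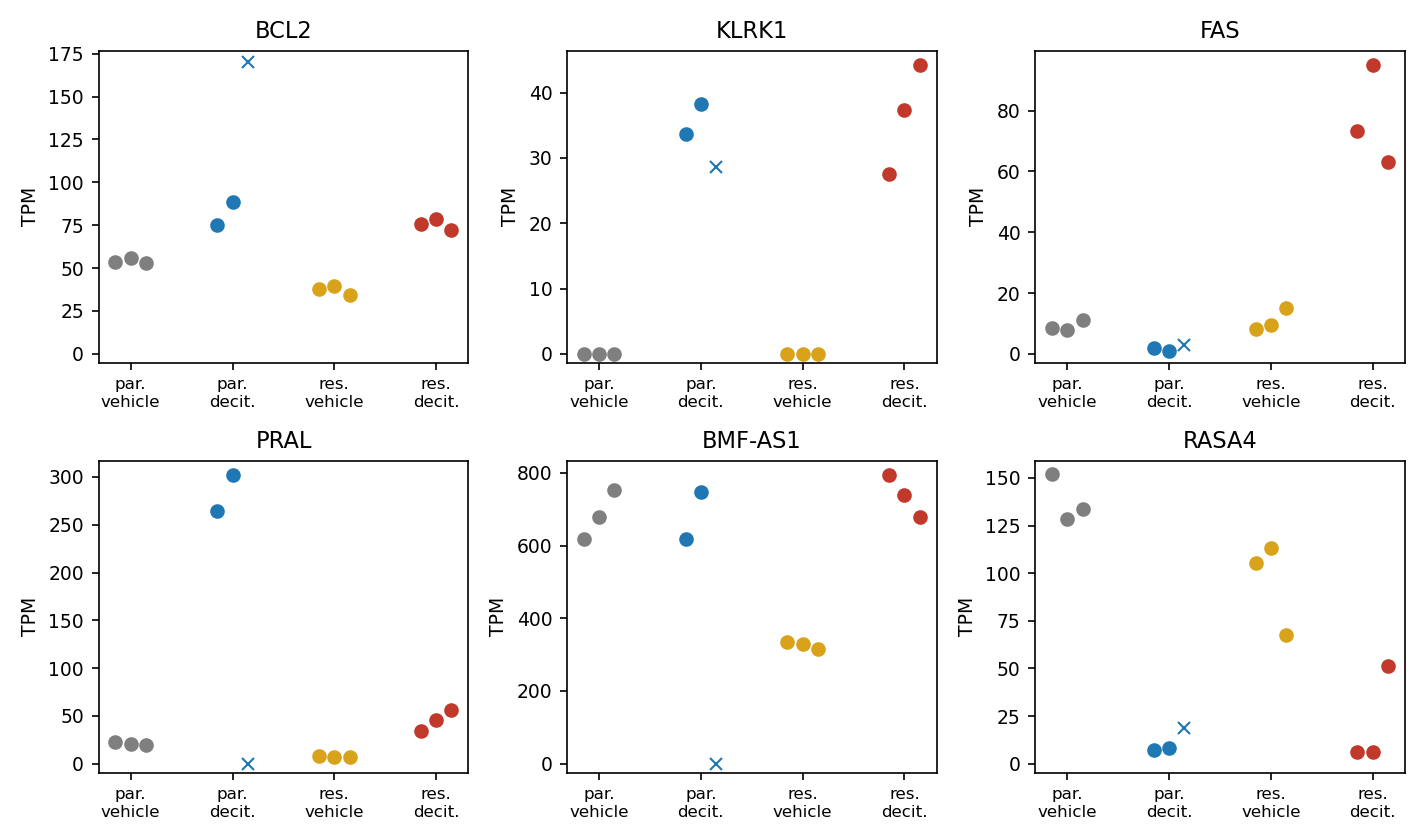
TPM per library (vertical axes) of BCL2, KLRK1, FAS, PRAL, BMF-AS1 and RASA4 in the 4 groups, 1 point per library, with parental decitabine replicate 3 as a cross. BCL2 in resistant cells was 37.1 TPM on average under vehicle and 75.5 TPM under decitabine.

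No fixed list passed camera in resistant cells (0 of 24 lists, 3 at an unadjusted p under 0.05). The mitochondrially encoded transcripts had a median log2 fold change of 0.89, with 0 of 13 past the threshold over all features and 7 adjusted over the list alone (camera adjusted p = 0.0807). Replication-dependent histones had a median of 1.21 over 4 tested members (camera adjusted p = 0.0807, fry adjusted p = 0.00193). Among 10 tested genes of decitabine uptake and nucleotide metabolism, SAMHD1 and DTYMK rose (fry adjusted p = 0.00254), and DTYMK lost its call without vehicle a, b or c (adjusted p = 0.0717, 0.0912 and 0.0977) or decitabine a, b or c (0.0877, 0.0743 and 0.079). FAS was the only call among 5 tested death receptor genes, PDK1 among 14 glycolysis genes and DDIT4 among 11 stress-response genes, where it lost its call without vehicle a, b or c (adjusted p = 0.0956, 0.127 and 0.0577) or decitabine a, b or c (0.0917, 0.13 and 0.138). None was called among the tested members of 5 further lists. These were 8 of 41 interferon-stimulated genes, 3 of 17 genes of the DNA methylation machinery and 8 of 11 pro-apoptotic BCL2 family genes. The others were 18 of 35 germinal-centre genes and 27 of 32 ribosomal protein genes. The remaining members were not tested, so an absent response of these lists cannot be concluded. In the glycolysis and stress-response lists camera's direction was down while the medians were 0.12 and 0.26, below or near the 0.21 of all features.

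Leaving out resistant vehicle a, b or c gave 197, 137 or 100 calls in place of 308, and leaving out decitabine a, b or c gave 104, 113 or 90. In 110 of the 308 (35.7%) every library of 1 group was listed at 0; all 308 separated the groups, as did 2434 of 8579 features tested (28.4%, with 10% by chance). The median log2 fold change of all features was 0.21, 0.10 under median-ratio scaling (220 rose and 124 fell) and -0.06 under quantile scaling (131 rose and 65 fell).

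Resistant against parental cells under vehicle addresses what differs once cells tolerate venetoclax, before any decitabine. In resistant cells 134 features were higher and 83 lower among 7761 tested. PPP2R1A, the scaffold subunit of protein phosphatase 2A, and the chromatin assembly gene CHAF1A were higher in vehicle libraries. The kinase gene MAP4K1 and CDR1 were lower. BCL2 was lower in 3 of 3 resistant libraries but passed only when adjusted over the list alone.

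PPP2R1A (chromosome 19, 52190039 to 52229533) was listed at 0 in the parental vehicle libraries and at 122, 183 and 149 TPM in the resistant ones (adjusted p = 0.000213). Under decitabine it was at 78.5, 0 and 105.6 TPM in parental and 0, 137 and 127 TPM in resistant libraries, and so at 0 in libraries of both lines. CHAF1A (chromosome 19, 4402662 to 4445018) was listed at 0 in the parental libraries and at 32.3, 33.6 and 37.2 TPM in the resistant ones (adjusted p = 0.000687), and under decitabine resistant libraries a and b were listed at 0. RINT1 was listed at 0 in the parental libraries and at 32.8, 34.9 and 39.9 TPM in the resistant ones (adjusted p = 0.000687), with 19.1, 0 and 32.4 TPM in parental decitabine libraries. MAP4K1 (chromosome 19, 38587641 to 38618882) was at 214, 258 and 209 TPM in the parental libraries and listed at 0 in the resistant ones (adjusted p = 5.97e-05), while resistant decitabine a and b had 156 and 153 TPM and c was listed at 0, as was parental decitabine replicate 1. CDR1, which lies over its whole length opposite LINC00632, was lower in resistant cells, at 48.5, 68.9 and 32.6 TPM in the parental libraries and 1.12, 1.17 and 0.48 TPM in the resistant ones (log2 fold change -4.68, SE 0.35, adjusted p = 0.00484). BCL2 had a log2 fold change of -0.53 (SE 0.12, adjusted p = 0.0908 over all features, 0.0167 adjusted over the list alone). Camera called 0 of 22 lists (0 at an unadjusted p under 0.05), and CHAF1A was the only list member called (G1/S list, fry adjusted p = 0.0147).

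The design had this comparison run only where raw counts share a scale. It was run because TPM are scaled the same way in every library over the same features, which was decided after the files were seen, and cell line and table cannot be separated. Leaving out parental vehicle replicate 1, 2 or 3 gave 63, 58 or 67 calls in place of 217, and leaving out resistant vehicle b or c gave 125 or 67. In 52 of the 217 (24.0%) every library of 1 group was listed at 0; all 217 separated the groups, as did 2179 of 7761 features tested (28.1%, with 10% by chance). The median log2 fold change of all features was 0.11, -0.02 under median-ratio scaling (84 higher and 97 lower) and 0.02 under quantile scaling (86 higher and 98 lower).

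The difference of the decitabine response between the lines addresses whether resistant cells answer the drug otherwise than parental cells. FAS rose with decitabine in resistant cells and was lower than under vehicle in parental decitabine replicates 1 and 2. Outside parental decitabine replicate 3, SNAP29 and ZC3HC1 were listed at 0 except under decitabine in resistant cells. UQCR10 rose in parental cells and was listed at 0 throughout resistant cells. The BCL2 response did not pass a test of difference.

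Without replicate 3, 16 features responded more and 15 less in resistant cells among 8505 tested. FAS was at 8.63, 7.89 and 11.1 TPM in parental vehicle and 1.81 and 0.88 TPM in parental decitabine libraries, against the rise in resistant cells (difference of log2 fold changes 4.87, SE 0.43, adjusted p = 0.0019). SNAP29 (chromosome 22, 20858983 to 20891218) was listed at 0 in 8 libraries and at 30.4, 35.1 and 23.4 TPM in resistant decitabine libraries (adjusted p = 0.00118), with 34.3 TPM in parental decitabine replicate 3. ZC3HC1 was at 18.2, 22.6 and 21.2 TPM in resistant decitabine libraries (adjusted p = 0.0013), with 60.5 TPM in parental decitabine replicate 3. UQCR10 had an adjusted p of 1.31e-05 without replicate 3, and TANGO2, which was listed at 0 in parental vehicle and at 36.6 and 44.2 TPM in parental decitabine libraries, had an adjusted p of 0.000579. Features opposite SNAP29 and TANGO2 had means of 94.1 and 19.4 TPM in the 11 libraries other than parental decitabine replicate 3. If strand was assigned oppositely, a value listed at 0 need not be that of the gene. For BCL2 the difference was 0.42 (limma adjusted p = 0.463). Camera called 0 of 22 lists (0 at an unadjusted p under 0.05).

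With all 12 libraries, limma called 1 feature, UQCR10 (adjusted p = 0.00129), of 12706 tested (341 at an unadjusted p under 0.05). FAS then had an adjusted p of 0.167 (0.00194 to 0.167 over its alternatives), SNAP29 0.709 (0.00113 to 0.709), ZC3HC1 0.709 (0.00113 to 0.709) and TANGO2 0.184 (0.000503 to 0.184). Leaving out parental decitabine replicate 3 gave 31 calls, parental vehicle replicate 1 gave 3, parental decitabine replicate 1 gave 2, resistant vehicle b gave 3 and resistant decitabine a gave 4. In 15 of the 31 (48.4%) every library of at least 1 group was listed at 0. From the 31, leaving out parental vehicle replicate 1, 2 or 3 as well gave 17, 13 or 12, resistant vehicle b or c gave 19 or 14, resistant vehicle a gave 47, and resistant decitabine c gave 14.

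The shared direction of the response addresses whether the same features answer decitabine in both lines. Without replicate 3, KLRK1, MID1IP1-AS1, PRAL, the long non-coding RNA PICSAR and its neighbour LINC00163 rose in both lines. H4C9 and the mitochondrial tRNA MT-TM rose in both lines too. ZBTB45 and DDIT4-AS1, which lies over its whole length opposite DDIT4, fell in both. No feature was called in opposite directions.

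Of 7359 features tested in both lines without replicate 3, 20 rose in both, against 2.85 by chance (Fisher's exact test p = 3.87e-12), and 7 fell in both, against 0.33 by chance (p = 2.75e-08). These chance counts and p take features as independent and do not allow for the library-wide shift common to both lines. The fold changes correlated across features with Spearman rho 0.313 and Pearson r 0.275, and 63.4% had the same sign. With all libraries, 7797 features gave Spearman rho 0.273, Pearson r 0.247 and 58.9% of the same sign. PICSAR was listed at 0 in parental vehicle and at 12.2 and 10.9 TPM in parental decitabine replicates 1 and 2, with replicate 3 at 0, and rose from at most 0.95 TPM to 45.3, 39.9 and 44.3 TPM in resistant cells. MT-TM rose from 177, 191 and 195 TPM to 853 and 1032 TPM in parental cells (log2 fold change 2.32) and from 228, 155 and 310 TPM to 856, 701 and 808 TPM in resistant cells (1.82). ZBTB45 fell from 158, 142 and 149 TPM to 70.1 and 64.2 TPM in parental cells (log2 fold change -1.15) and from 86.6, 95.8 and 88.9 TPM to 35.4, 38.7 and 36.5 TPM in resistant cells (-1.27). PICSAR, LINC00163, H4C9, MT-TM, ZBTB45 and DDIT4-AS1 were chosen after their values were seen. In parental cells PICSAR lost its call without vehicle replicate 1, 2 or 3 (adjusted p = 0.0809, 0.0822 and 0.0655, range 0.0117 to 0.594), MT-TM without vehicle replicate 1 or 2 (0.0592 and 0.0541, range 0.0046 to 0.594), ZBTB45 without vehicle replicate 1, 2 or 3 or decitabine replicate 2 (0.104, 0.109, 0.094 and 0.0514), DDIT4-AS1 likewise (0.106, 0.121, 0.098 and 0.0534), and H4C9 and LINC00163 without any 1 of the 5 libraries (lowest 0.0807 and 0.0804). In resistant cells MT-TM lost its call without vehicle a and decitabine a, b or c (adjusted p = 0.0661, 0.0934, 0.0744 and 0.0886), ZBTB45 without vehicle c (0.0502), and DDIT4-AS1 without vehicle b or c and decitabine a, b or c (0.0774, 0.0752, 0.0985, 0.101 and 0.108).

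**Figure D4:**
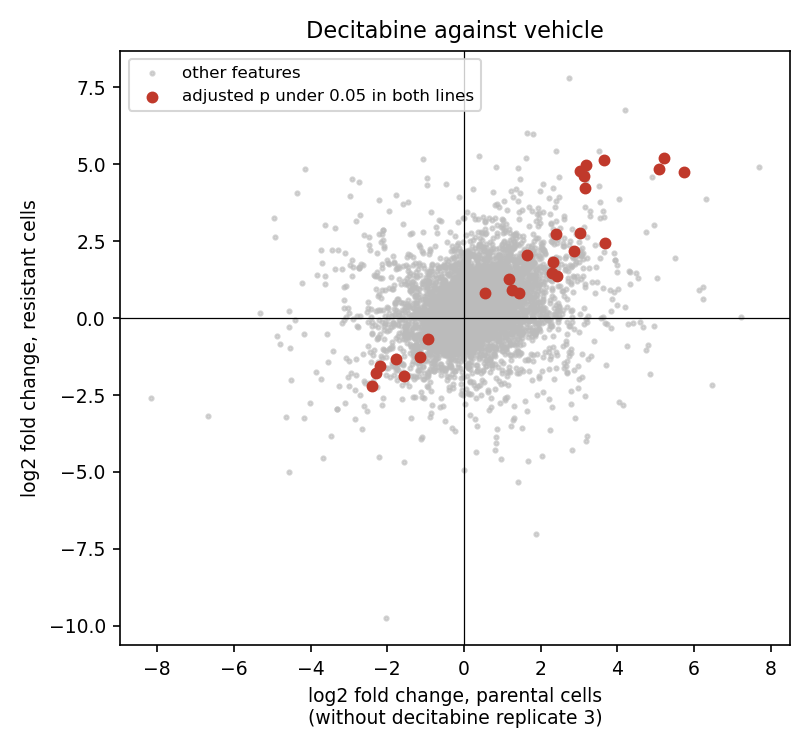
Log2 fold change of decitabine against vehicle in parental cells without replicate 3 (horizontal axis) and in resistant cells (vertical axis), 1 point per feature tested in both, with features of adjusted p under 0.05 in both lines in red. The red points lie in the upper right (20 features) and the lower left (7 features).

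The overlap of the resistance difference with the decitabine response addresses whether decitabine moves resistant cells toward or away from parental levels. In resistant cells 36 features were called in opposite directions and 7 in the same direction, in comparisons that share the resistant vehicle libraries. BMF-AS1, which lies opposite the pro-apoptotic gene BMF, the metabolic gene ACAT1 and the mitochondrial kinase gene PINK1 were lower in resistant cells and rose. RUSC1-AS1 was higher and fell.

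Of 7377 features tested in both comparisons, 19 were lower in resistant cells and rose with decitabine (1.16 by chance), and 17 were higher and fell (1.18 by chance), while 6 were higher and rose (2.43 by chance) and 1 was lower and fell (0.56 by chance). BMF-AS1 (chromosome 15, 40088832 to 40089386) was at 619, 678 and 753 TPM in parental vehicle libraries, and rose in resistant cells from 335, 330 and 316 TPM to 794, 740 and 680 TPM (log2 fold change 1.17, SE 0.10, adjusted p = 0.0084). PINK1 was at 24.3, 20.5 and 20.6 TPM in parental vehicle libraries, and rose in resistant cells from 7.33, 5.87 and 5.46 TPM to 35.2, 26.2 and 27.9 TPM (log2 fold change 2.09, adjusted p = 0.0127). ACAT1 was at 59.5, 88.0 and 91.1 TPM in parental vehicle libraries, and in resistant cells at 0, 3.61 and 0 TPM under vehicle and 61.6, 74.2 and 56.9 TPM under decitabine. RUSC1-AS1 was at 824, 855 and 922 TPM in parental vehicle libraries, and fell in resistant cells from 1477, 1787 and 1626 TPM to 640, 656 and 725 TPM (log2 fold change -1.27, adjusted p = 0.0084). BMF-AS1, PINK1 and RUSC1-AS1 were chosen after their values were seen. In the parental decitabine libraries without replicate 3, 8 features that were higher in resistant cells rose (1.24 by chance) and 4 that were lower fell (0.44 by chance), while 3 that were lower rose (0.87 by chance) and 0 that were higher fell (0.63 by chance).

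In resistant cells both comparisons share the resistant vehicle libraries, which makes opposite directions more frequent with no effect at all. For the parental response the shared libraries are the parental vehicle ones, which makes the same direction more frequent. The counts by chance allow for neither. The covariance of the fold changes was -0.432. Unchanged groups drawn as normal noise, with a vehicle group shared in the same way, gave -0.347 (SD 0.0204, 100 simulations), a difference of -0.0848. All libraries were drawn anew with each feature's spread, and values that switch between 0 and high were not modelled. The Pearson correlation was -0.435 and the simulated one -0.504, closer to -1. In parental cells without replicate 3 the covariance was 0.435 and the simulated value 0.342 (SD 0.024), and Pearson r was 0.434 against 0.445. With all parental libraries the covariance was 0.406 and the simulated value 0.816. The counts of calls were not simulated, and the vehicle libraries are too few to be split, so how much of the overlap comes from the shared libraries stays open. The 36 features of opposite direction became 11, 5 and 9 without parental vehicle replicate 1, 2 and 3, 16 and 9 without resistant vehicle b and c, and 12, 14 and 10 without resistant decitabine a, b and c. BMF-AS1 was no longer called lower in resistant cells without parental vehicle replicate 2 or resistant vehicle c (adjusted p = 0.0575 and 0.0563, range 0.00527 to 0.0575). PINK1 lost its rise without resistant decitabine c (adjusted p = 0.0519, range 0.0171 to 0.0519), and its lower level without parental vehicle replicate 1, 2 or 3 and resistant vehicle b or c (0.0911, 0.0849, 0.0787, 0.0523 and 0.0743). RUSC1-AS1 was no longer called higher without parental vehicle replicate 1, 2 or 3 or resistant vehicle c (adjusted p = 0.0776, 0.0833, 0.0639 and 0.0762). ACAT1 lost its rise without resistant vehicle c or decitabine a, b or c (adjusted p = 0.0577, 0.0725, 0.0672 and 0.0681, range 0.00395 to 0.0725), and its lower level without parental vehicle replicate 1, 2 or 3 or resistant vehicle c (0.0742, 0.088, 0.0846 and 0.0737).

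Most other genes named before the data were examined were near 0 in the 11 libraries. MCL1 was at 0 to 3.10 TPM in the 11 and at 56.3 TPM in parental decitabine replicate 3, DNMT1 at 0 to 2.40 against 220.6 TPM, DNMT3A at 0 to 0.22 against 2.50 TPM, CDKN1A at 0 to 2.48 against 112 TPM, BAX at 0 to 7.53 against 125 TPM and DCK at 0 to 3.16 against 53.4 TPM. DNMT3B was listed at 0 in the 11 and at 5.68 TPM in replicate 3. BCL2L11 was at 3.79 to 18.9 TPM in the 11, PMAIP1 at 0.19 to 10.6 TPM, BBC3 at 0 to 2.32 TPM and BCL2L1 at 2.07 to 32.5 TPM. BAK1 was listed at 0 in most of the 11. Of markers of other cell types, those of T and NK cells summed to 0.4 to 5.7 TPM in the 11 libraries and 209 TPM in replicate 3, where LCK had 143.7 TPM. Epithelial and stromal markers summed to 34.8, 22.6 and 1.9 TPM in resistant decitabine libraries, mostly KRT8 (22.4, 14.5 and 1.8 TPM), and to at most 4.0 TPM in the other libraries of the 11. Myeloid markers summed to at most 4.8 TPM and erythroid markers to at most 2.7 TPM in the 11. With all libraries, camera called 8 of 27 lists in parental cells and 9 of 27 for the difference between the lines, 0 of them with an estimated correlation. Without replicate 3, 1 of these 17 was called, the mitochondrially encoded transcripts in parental cells.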

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

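All tests weighing explanations in this part were chosen after the results were seen, while the test of the difference between the lines and the count over other splits were planned.

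The test of a different decitabine response in resistant and parental cells singled out FAS, SNAP29, ZC3HC1, UQCR10 and TANGO2 without parental decitabine replicate 3. With all libraries only UQCR10 of these was called. It called 1 feature with all libraries and 31 without parental decitabine replicate 3. Splits of the libraries within each line were drawn, 100 in each case. With all libraries 57 of the 100 gave at least 1 call, so chance cannot be excluded for the count. The highest, 38, came from a split with the treatments of resistant cells exchanged. There the contrast added the responses of the lines, so the 38 are no measure of chance, and the highest of the others was 4. Without replicate 3, 5 of the 100 gave at least 31: the real one and 4 with 96 to 1004 calls, in which all decitabine libraries of 1 line stood on the vehicle side. In these 4 the contrast added the responses of the lines, which points to a structure of the libraries, so they are no measure of chance for a difference and the splits leave chance open there; the highest of the others was 19.

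Parental decitabine replicate 3 listed ACTB, EEF1A1, RPLP0 and CD79A at 1491 to 6353 TPM where the other 11 libraries listed them at 21 TPM or less. A decitabine response is argued against, since decitabine replicates 1 and 2 correlated with parental vehicle libraries at 0.911 or more, and replicate 3 at 0.321 or less. A different depth or yield is argued against too. Of 2761 coding genes of at least 20 TPM in replicate 3 without overlap on the opposite strand, 1.1% were within 2-fold in the mean of the other 11 libraries. A wider set served as background: of all features of at least 20 TPM in decitabine replicate 1, 89.3% were within 2-fold in replicate 2. A candidate explanation is that strand was assigned oppositely in replicate 3 and in the other 11 libraries, since features opposite a gene followed that gene's level in replicate 3 (rho 0.641, 0.608 to 0.692 over 18 filters) more than their own (0.104, 0.06 to 0.217). Under it, coding genes in the 11 libraries may be listed largely by reads assigned to the wrong strand, and the raw reads, not analysed here, would decide.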

How the results depend on the processing

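Features above 0 in every library, median-ratio scaling outside the list tests, list tests without replicate 3 and further settings of the fits without replicate 3 were chosen after the data were seen, and the other tests were planned; for each change given here the cause was not tested unless stated.

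Parental decitabine: 0 calls became 0 to 151 with 1 library left out, and 79 without replicate 3 over features above 0; the other settings gave 0. With the replicate block in parental cells the count was 0, and without replicate 3 it was also 0 with a block, which leaves fewer degrees of freedom. Without replicate 3 the 151 calls became 35 with no filter, 105 at a mean of at least 5 TPM, 102 with a pseudocount of 0.1, 23 at an adjusted p under 0.01, 138 with a 2-fold limit and 14 to 264 with 1 more library left out. Same-numbered parental libraries deviated together with r of -0.003, 0.016 and 0.022, and libraries did not all correlate best with their own number. These values include replicate 3, which stood far apart, so they cannot decide whether same-numbered libraries were paired. The block was not run in resistant cells, whose columns were matched to groups and not to single samples.

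Resistant decitabine: 308 calls became 196 with quantile scaling, 73 with no filter, 194 at a mean of at least 5 TPM, 39 at an adjusted p under 0.01 and 90 to 197 with 1 library left out. The other settings gave 267 to 344.

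Resistant against parental: 217 calls became 68 with no filter, 37 at an adjusted p under 0.01 and 58 to 191 with 1 library left out. The other settings gave 156 to 263.

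Difference between the lines: 1 call became 1 to 31 with 1 library left out, and 15 without replicate 3 over features above 0. Without replicate 3 the 31 calls became 7 with no filter, 25 at a mean of at least 5 TPM, 30 with a pseudocount of 0.1, 6 at an adjusted p under 0.01, 29 with a 2-fold limit and 12 to 47 with 1 more library left out.

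The shared direction stayed between rho 0.236 and 0.313 with 1 library left out, with 0.394 without replicate 3 over features above 0. The 36 features of opposite direction became 19 with a 2-fold limit and 5 to 32 with 1 library left out. For parental decitabine the count of features of the same direction, 0 with all libraries, became 0 to 12 with 1 library left out, and 8 without replicate 3 over features above 0.

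The 17 list calls became 0 with an estimated correlation and 1 without replicate 3. Fry called 0 of the 17 and 3 other lists, 2 in resistant cells and 1 between the lines. Without replicate 3 it called 1 list in parental cells, the mitochondrially encoded transcripts. The count was 17 with median-ratio scaling and 20 with the replicate block.

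Named features kept direction and call in 140 of 279 settings in parental cells without replicate 3, 205 of 256 in resistant cells, 131 of 168 between the lines and 109 of 210 for the difference of responses. Reversed were MT-ND6 in parental cells with replicate 3 included (log2 fold change -1.38, adjusted p = 0.786) and RUSC1-AS1 in the difference of responses with it included (1.45, adjusted p = 0.773). Alternatives for counts and library totals were not run, since the values are TPM. Comparisons of 2 groups within a fit of all 12 libraries were not run either. Depth is unknown, so what it limits cannot be given.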

Other observations

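All tests in this part were chosen after the results were seen, except the counts over other splits.

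Of features on the opposite strand of list genes, 23 were tested. BMF-AS1, opposite BMF, rose in resistant cells (log2 fold change 1.17) and had a log2 fold change of 0.00 in parental cells without replicate 3 (adjusted p = 0.985), a difference with an adjusted p of 0.0346. That difference was no longer called without parental vehicle replicate 2 or 3 (adjusted p = 0.0735 and 0.0715), parental decitabine replicate 1 (0.0695), resistant vehicle b or c (0.0503 and 0.0714), or resistant decitabine a, b or c (0.0521, 0.0512 and 0.0511; range over its alternatives 0.0192 to 0.709). The feature opposite MDM2 rose from 260, 237 and 319 TPM to 608 and 691 TPM in parental cells (1.26, SE 0.16, adjusted p = 0.0454) and from 700, 677 and 853 TPM to 1317, 1450 and 1430 TPM in resistant cells (0.92, SE 0.12, adjusted p = 0.0247), and was higher in resistant than parental vehicle libraries (1.45, SE 0.16, adjusted p = 0.017). DDIT4-AS1, opposite DDIT4, fell from 1573, 1659 and 1985 TPM to 466 and 305 TPM in parental cells (-2.20, adjusted p = 0.031) and from 1129, 648 and 616 TPM to 279, 258 and 236 TPM in resistant cells (-1.57, adjusted p = 0.0358), with the libraries its calls rest on given in the report. PRAL, opposite XAF1, rose in both lines. The features opposite MDM2, GAPDH and PA2G4 were not retested with libraries left out. The feature opposite GAPDH fell in parental cells (-0.86, adjusted p = 0.0284) and that opposite PA2G4 in resistant cells (-0.91, adjusted p = 0.0457). In parental cells without replicate 3, 2 of the 23 rose and 2 fell over all features, and in resistant cells 3 rose and 2 fell. If strand was assigned oppositely in the 11 libraries (rho 0.641), these features may carry the level of the gene they lie opposite, so that BMF, MDM2 and XAF1 would rise and DDIT4 fall.

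PRDX2, H2BC12 and MAP4K1 were listed at 0 in some libraries and at high TPM in others, and such switching also occurred within groups, in 7.5% to 14.3% of features with at least 10 TPM in some library of the group. In resistant cells, failed estimates unrelated to treatment are argued against as the whole cause: of 106 features at 0 in 3 and at 10 TPM or more in 3 resistant libraries, 22 (20.8%, exact 95% interval 13.5% to 29.7%) separated by treatment, against 11.4 by chance at each library's own rate (exact binomial p = 0.00236, with features taken as independent). About 11 of the 22 would still be reached by chance, so a single such feature may not be a treatment response. Between the vehicle libraries of the lines (16.3%, interval 9.6% to 25.2%, chance 9.9%, exact binomial p = 0.0419) and in parental cells without replicate 3 (8.2%, 3.6% to 15.6%, chance 6.3%, p = 0.4, with 2 libraries at 0; 19.8%, 13.1% to 28.1%, chance 13.2%, p = 0.0424, with 3), failed estimates cannot be told apart from an effect, since the intervals include chance, though 2 of the 3 p are under 0.05. Overlap with another feature on the same strand is argued against as the whole source. Switching within a group of resistant cells affected 17.2% of 4015 features without such overlap. It affected 14.8% of 656 features with no exon overlap on either strand. With same-strand overlap the share was 24.2% of 681, so overlap as a part of the source cannot be told apart.

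Mitochondrially encoded transcripts had higher values with decitabine in parental cells without replicate 3, though the list did not pass with an estimated correlation (adjusted p = 0.644). Scaling to 1000000 moves every feature of a library alike, and is argued against as the whole cause: the 8109 features outside the list had a median log2 fold change of 0.21 (quartiles -0.25 and 0.70), below the list's lower quartile of 0.88. A response to decitabine stays open, and so does a difference in RNA yield or strand assignment between libraries, which may act on this list by itself.

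The 6 libraries of each pair of groups, or 5 without replicate 3, allow 10 splits, too few for a share under 0.05. BCL2, FAS and SAMHD1 were among 308 calls in resistant cells, reached by 1 of the 10 splits, with 15 as the highest other. MAP4K1 and CHAF1A were among 217 calls between the lines, reached by 1 of 10, with 21 as the highest other. Without replicate 3, 151 calls in parental cells were reached by 1 of 10, with 27 as the highest other. With all parental libraries, 0 calls were reached by 10 of 10, with 5 as the highest other.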
